A study of Homo sapiens with 25 samples.

How the data were processed

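The series holds gene counts of 12 RNA sequencing libraries from sorted cells and probe counts of 12 regions from xenograft tumours. The sorted cells came from A673 and CHLA10, both established Ewing sarcoma lines, each separated into cells with and without CD73 on the surface, with 3 libraries in each of the 4 groups. CD73, encoded by NT5E, is a surface enzyme that makes adenosine from AMP. Per the labels, A673 grew in RPMI with 10% serum, whereas CHLA10 grew in IMDM with 20% serum and insulin, transferrin and selenium, so line and medium go together in every comparison of the lines. RNA was purified on RNeasy columns and libraries were made with the NEBNext Ultra II kit. Nothing in the labels says that the 3 replicates of a group were separate cultures. The tumours were xenografts in NSG mice, labelled CHLA10 throughout, with 1 subcutaneous tumour and 2 tumours after tail vein injection (1 in the liver and 1 retroperitoneal), each from its own animal and sampled in 4 regions. The subcutaneous tumour was taken 54 days after injection of 400000 cells, and the tail vein tumours 28 days after injection of 700000 cells, so route, site, day and cell number cannot be separated.

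Reads of the sorted cells were trimmed with Trim Galore 0.6.7 and aligned to hg38 with STAR 2.7.9a by the authors, who deposited STAR's counts of reads per gene, a raw count for each of 33538 genes. The unstranded column was used, since the share of one strand's column among both strand columns lay between 49.7% and 50.3%. Symbols were found for 33113 gene identifiers in a table of gene names and for 343 more in GENCODE 29, and 82 stayed without one. The annotation release behind the counts is not given in the sources used here, and the positions printed are from GENCODE 29 on hg38.

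The regions were measured with the GeoMx human whole transcriptome probe panel on formalin-fixed sections that shared 1 slide, with barcodes read by sequencing. The deposited workbook gives, per target, deduplicated probe counts after the authors' quality control, which are expected counts because the negative probe value is a mean over probes. It also gives area-normalised values, a signal equal to the count divided by 1 constant per region, and Q3-normalised values, a signal in which the authors scaled each region to a common upper quartile. Nuclei and read counts per region, the surface area (another unit, of the region itself), the percent sequencing saturation and a limit of quantitation were deposited beside them. The probe count sheet holds 18677 targets and the Q3 sheet 13389. The Q3 targets were those above the limit of quantitation in at least 1 region, with 2 exceptions. The no template control and the target summary sheet were not used here.

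Sorted-cell counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (15634 genes), libraries were scaled by TMM, and all 12 libraries entered 1 quasi-likelihood fit of 4 group means. Tested were CD73 positive against negative cells in each line, the difference between those effects, and CHLA10 against A673 among CD73 negative cells. P values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Levels are counts scaled to the library total (CPM) with the SD over 3 libraries, and fold changes are log2 with their SE. Gene lists, 30 in all, were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it. NT5E was left out of every list, since CD73 was the marker of the sort, and 29 lists had enough members, the erythroid list having too few. The lists, groups, tests, thresholds, alternatives and the rule for named genes were fixed before the data were examined.

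Whether replicate numbers pair the negative and positive libraries of a line was checked by the correlation of their deviations from group means. Same-numbered libraries correlated at 0.746, 0.470 and 0.510 in A673 and at 0.273, 0.281 and 0.177 in CHLA10, all above the preset minimum of 0.1. Values from a fit with the replicate number as a block are therefore given beside the counts. In A673, however, negative 2 with positive 3 (0.340) and negative 3 with positive 2 (0.338) passed that minimum too. It thus does not show that replicates 2 and 3 of A673 pair by number. No pair of libraries within a group was a copy of another, as their counts differed by a chi-square of 10.5 to 53.2 per degree of freedom.

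For the regions, Q3 values were taken to log2 with a pseudocount of 1. Targets were kept when above 2 times the negative probe value in at least 4 regions (10208 targets). Each animal's mean over its regions was fitted with limma's trend method, tail vein against subcutaneous, with 1 residual degree of freedom. These p values therefore rest on the difference between 2 tail vein animals, and the subcutaneous animal is assumed to vary alike. A second measure counted targets separated by size, where every region of one side lay above every region of the other and the mean difference was at least 1 on the log2 scale (for each of the 2 tail vein animals, where these were compared with the subcutaneous one). Lists were tested with camera on the animal means, planned for the CD73 lists from the sorted CHLA10 cells and added for the fixed lists after the data were seen, but as 1 arm is 1 animal their p values are left out of the text. Spread between regions of a tumour was compared with 10000 random lists matched on level. The comparison of the regions with the sorted cells of each line was also added after the data were seen.

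Named genes were NT5E, a fixed panel of 14, the 10 highest and 10 lowest fold changes among genes that passed with a level of at least 5 CPM and no overlap between groups (5 each way for the differences between lines), and up to 4 members of each called list. Some genes named by these rules are not reported here, nor counted among the named genes under alternatives. Y-linked genes and XIST were left out of naming and of the tables of all genes. Alternatives were DESeq2 1.42.0, its size factors in edgeR, limma-voom, other filters, the other counting column, each line fitted alone, the replicate block, each library or region left out, other pseudocounts, area-normalised values and TMM. Leaving out both A673 libraries of replicate 1, subtracting the negative probe value and leaving out retroperitoneal regions 9 and 10 were added after the data were seen. Sorted-cell counts were simulated from the CD73 negative means of both lines, with changes placed in the CD73 positive A673 libraries. Of these, 54% of 2-fold and 86% of 4-fold changes were recovered, with 12 false calls among 152, and no comparison without change gave a call (0 calls). The simulated libraries varied independently, without variation shared by same-numbered libraries. These rates may therefore not hold for the real A673 comparison. For the regions, 83% of changes of 1.5 on the log2 scale were recovered by limma and 98% by the size rule. These simulated regions varied independently of each other, without variation between animals. The rates therefore do not describe a comparison in which the animal is the replicate. Tables and figures used Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Intervals and floors cover counting error only.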

Results

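Transcripts were counted in sorted cells of 2 Ewing sarcoma lines and in regions of 3 xenograft tumours. The sorted cells gave 4 groups of 3 libraries, A673 and CHLA10 cells with and without surface CD73. Each library held between 17697550 and 24471940 counts in genes (median 19252822), with 18112 to 19405 genes detected. Unmapped reads made up 2.13% to 3.23% and ambiguous reads 7.80% to 8.70%. The first principal component of the 12 libraries (74.2% of the variance) separated the lines, and the next (8.16%) separated CD73 negative from CD73 positive CHLA10 cells. A further component (7.14%) set both A673 libraries of replicate 1 apart from the other A673 libraries. The tumours gave 4 regions each, with 956144 to 12787050 deduplicated reads per region.

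In CHLA10 cells, those with CD73 differed widely from those without it, and genes of matrix, contraction and adhesion were among the higher ones. Of 15634 genes, 889 were higher and 513 lower in the CD73 positive cells, 1402 in all (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 libraries per group). NT5E itself (ENSG00000135318, hg38 chromosome 6, 85449584 to 85495791), the gene of CD73, went from 3.86 ± 0.636 to 86.2 ± 12.4 CPM (SD, n = 3), a log2 fold change of 4.48 ± 0.28 (SE, adjusted p = 1.24e-05 by edgeR). As the cells were sorted on CD73, this value describes the sort and is no finding. Among the fixed panel, TNC, a matrix glycoprotein of remodelling tissue, rose by 3.01 ± 0.32 on the log2 scale, from 151 to 1215 CPM (edgeR adjusted p = 1.62e-04). FN1 (fibronectin) rose by 3.32 ± 0.47, from 330 to 3293 CPM. LOX, which crosslinks collagen, rose by 1.77 ± 0.31, from 102 to 350 CPM. COL1A1 (1.77), CD44 (3.24), THY1 (0.88), VIM (1.77), TGFBI (4.39) and CCN2 (2.87) also rose. The fusion partner gene FLI1 (ENSG00000151702, hg38 chromosome 11, 128686535 to 128813267) at -0.02 ± 0.09 and the EWS::FLI1 target NR0B1 (ENSG00000169297, hg38 chromosome X, 30304206 to 30309598) at -0.15 ± 0.41 did not pass. COL1A2 (1.67 ± 1.19, edgeR adjusted p = 0.466) and ENG (0.38 ± 0.60) did not pass either, but did with the replicate block (edgeR adjusted p = 2.84e-05 and 0.0418).

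The highest fold changes in CHLA10 were those of CPA4 (a carboxypeptidase, 6.04), GFRA1 (a co-receptor for GDNF, 5.67), the collagen gene COL12A1 (5.50), DKK1 (a secreted Wnt inhibitor, 5.26), POSTN (periostin, 5.16), CRYAB (a small heat shock protein, 5.13), ANKRD1 (a target of YAP and TAZ, 5.05), GREM1 (a secreted BMP inhibitor, 4.99) and MARCHF4 (4.94). The lowest were those of OTX2 (-4.66) and TFAP2B (-4.64), which encode developmental transcription factors, NRK (-4.48), PLEKHS1 (-4.46), BTBD17 (-4.43), the calcium channel gene CACNA1A (-4.31), VAV1 (-4.26), LOXHD1 (-4.05) and DAB1 (-3.92). PSG4 (6.14, from 0.108 to 7.89 CPM) and MBD3L3 (-4.90, from 12.3 to 0.404 CPM) belong to families of near-identical copies, so which copy changed is uncertain.

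By gene list, 16 of 29 lists differed between CD73 positive and negative CHLA10 cells (camera, preset correlation of 0.01), 15 toward higher and 1 toward lower levels. Of 38 collagens and matrix glycoproteins, 20 rose, 3 fell and 15 did not pass, with 23 up and 4 down adjusted over the list alone. The median was 1.57, and examples are COL4A1 (2.01) and COL4A2 (2.11) of basement membranes and FBLN5 (3.16) of elastic fibres. This list's call was lost with an estimated correlation (adjusted p = 0.0608, camera). Of 32 matrix remodelling enzymes, 13 rose and 1 fell (19 and 4 adjusted over the list alone), among them MMP1 (4.92, a collagenase), LOXL2 (3.57) and ADAM19 (3.99). Of 22 cancer-associated fibroblast markers, which are genes of activated stroma, 13 rose and 1 fell (16 and 1 adjusted over the list alone), including ACTA2 (3.00), TAGLN (4.04) and CAV1 (1.56). Of 28 contractile and actin cytoskeleton genes, 21 rose and 1 fell (24 and 1 adjusted over the list alone), with ACTN1 at 1.67 and CALD1 at 1.72. Of 24 integrins and matrix receptors, 10 rose (14 up and 1 down adjusted over the list alone), among them the collagen receptor gene ITGA11 (4.43) and the syndecan gene SDC2 (2.97). Of 25 TGF-beta pathway genes and targets, 12 rose and 1 fell (13 and 1 adjusted over the list alone), including TGFB2 (3.12) and TGFBR2 (2.54). With an estimated correlation, the adjusted p by camera was 0.0200 for remodelling enzymes and for fibroblast markers, 0.0304 for contractile genes, 0.00754 for integrins and 0.0384 for TGF-beta.

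Targets of EWS::FLI1, the fusion transcription factor that drives most Ewing sarcomas, moved apart in CHLA10 by the direction of their known control. Of 29 repressed targets, 18 rose (20 up and 1 down adjusted over the list alone), with a median of 1.61 and with ZYX (1.16) and ANXA2 (1.55) among them. Of 30 activated targets, 11 fell (13 down and 1 up adjusted over the list alone), with a median of -0.33 and with STEAP1 (-1.29), STEAP2 (-1.47), IL1RAP (-0.60) and SOX2 (-1.06) as examples. Both calls held with an estimated correlation (adjusted p = 0.0107 and 0.0304, camera). Of 22 YAP and TAZ targets, 13 rose and 1 fell (14 and 1 adjusted over the list alone), including CRIM1 (2.61) and MYOF (3.56), but the call was lost at an adjusted p = 0.0556 with an estimated correlation (camera). Of 18 mesenchymal stem cell surface markers, 11 rose (11 up and 1 down adjusted over the list alone), with ITGAV at 1.09 and ITGA5 at 0.83 (adjusted p = 0.0947 with an estimated correlation). Of 21 mesenchymal transition regulators, 7 rose and 3 fell (9 and 4 adjusted over the list alone), CDH2 (N-cadherin) rising by 4.47 and HMGA2 by 2.28 (adjusted p = 0.0635 with an estimated correlation).

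Smaller shifts were called in 5 further lists in CHLA10, and each was lost with an estimated correlation. Of 17 antigen presentation genes, 4 rose (5 adjusted over the list alone), including HLA-C (1.39) and HLA-B (2.28), whose close sequence copies leave their separate levels uncertain (adjusted p = 0.139 with an estimated correlation, camera). Of 28 hypoxia and glycolysis genes, 4 rose (5 adjusted over the list alone), among them ADM (2.43) and PKM (0.75), at an adjusted p = 0.139 with an estimated correlation. Of 23 genes of the unfolded protein and integrated stress responses, 2 rose (7 adjusted over the list alone), PPP1R15A by 0.78 and HSP90B1 by 0.35 (adjusted p = 0.121 with an estimated correlation). Of 25 immediate early and dissociation stress genes, 5 rose (5 up and 1 down adjusted over the list alone), including IER3 (1.81) and EGR1 (from 12.3 to 34.9 CPM), at an adjusted p = 0.412 with an estimated correlation. Of 24 cholesterol synthesis genes, 1 rose (0 adjusted over the list alone, by edgeR), NSDHL by 0.37 (adjusted p = 0.762 with an estimated correlation). The medians of the remaining lists, none of which was called, lay at -0.06 for proliferation, -0.04 for type I interferon-stimulated genes, 0.05 for NF-kappaB and inflammatory genes, -0.24 for Wnt and beta-catenin targets, 0.06 for p53 targets, 0.08 for neuronal and neuroendocrine genes, 0.03 for adenosine metabolism and receptors, and -0.08 for mitochondrially encoded transcripts. The lists of other cell types, with 4 to 12 members tested, had medians of -0.23 (hepatocyte), 0.11 (endothelial), -1.70 (leukocyte), -0.44 (muscle and adipose, where camera's direction was upward) and -0.50 (keratinocyte).

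With the replicate block, 3958 genes were called in CHLA10 (2199 higher, 1759 lower), and with the block and an estimated correlation no list's adjusted p by camera lay below 0.218. The count fell to 795 without CD73 negative replicate 1, 809 without CD73 positive replicate 1 and 754 without CD73 positive replicate 3, and rose to 2266 without both A673 libraries of replicate 1.

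**Figure D1:**
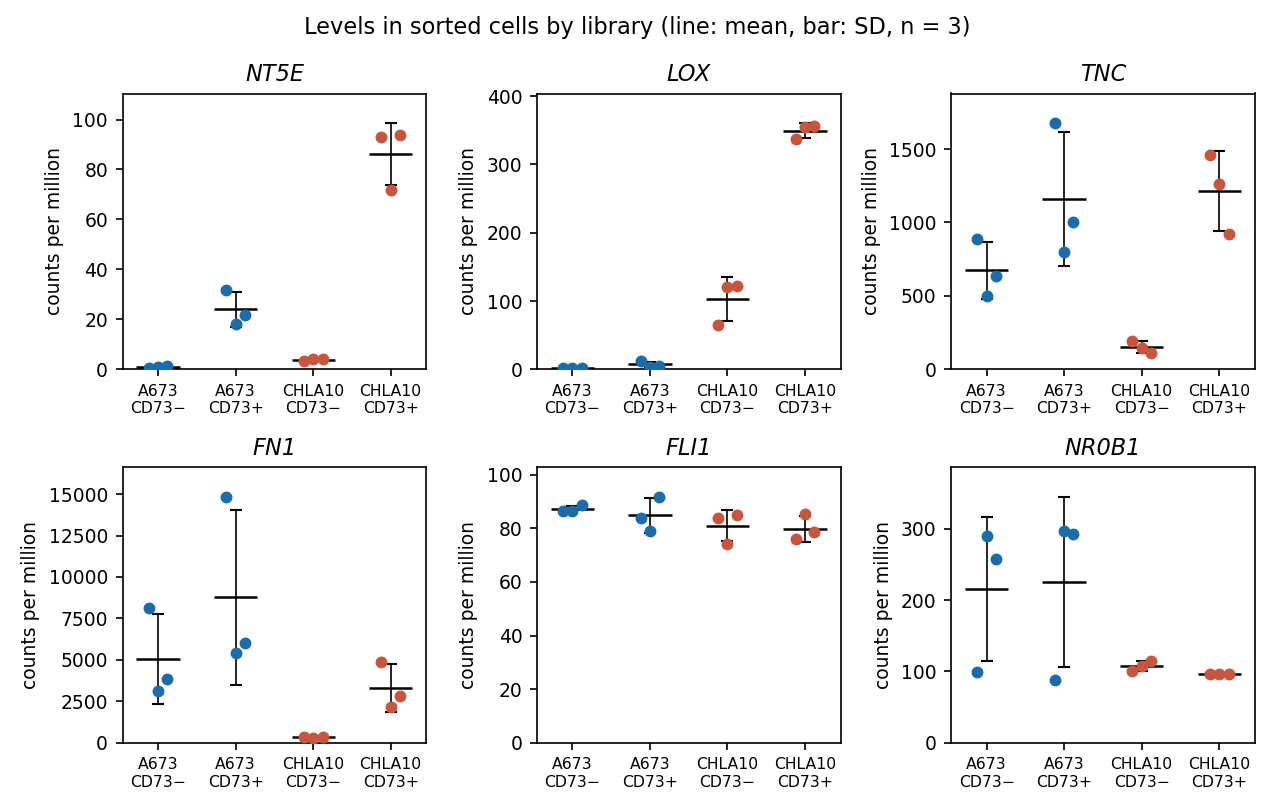
Levels of 6 genes in CPM (linear axis from 0) for each of the 12 sorted-cell libraries, with the mean as a line and the SD as a bar (n = 3 per group). TNC and LOX were higher in all 3 CD73 positive than in all 3 CD73 negative CHLA10 libraries, FLI1 lay between 79.9 and 87.1 CPM in the group means, and NR0B1 was lower in both A673 libraries of replicate 1.

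In A673 cells, the same comparison passed for 1 gene, NT5E, which went from 0.784 ± 0.379 to 24.0 ± 7.06 CPM (SD, n = 3), a log2 fold change of 4.92 ± 0.32 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.97e-05). At an unadjusted p under 0.05 there were 558 genes, and the count that passed was 33 by DESeq2 and 3 by limma-voom. With each line fitted alone in edgeR it was 0, with 439 genes at an unadjusted p under 0.05. Both 558 and 439 lie below a share of 0.05 of the genes tested (15634 and 14452), which chance alone would give. They are thus no sign of further differences. Nor do they show that there are none, as these fits leave the replicate number out. The collagenase gene MMP1 stood at 394 CPM in CD73 negative and 1515 CPM in CD73 positive cells (1.94 ± 0.26, edgeR adjusted p = 0.0671), and CD44, a receptor for hyaluronan, at 2.68 and 14.1 CPM (2.39 ± 0.42, adjusted p = 0.368). LOX measured 1.57 ± 0.39 and TNC 0.79 ± 0.30, neither of which passed. FLI1 measured -0.04 ± 0.09 and NR0B1 0.07 ± 0.41.

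Matrix and adhesion genes were nevertheless higher as groups in CD73 positive A673 cells. Of 29 lists, 10 were called toward higher and 1 toward lower levels by camera, although no member passed over all genes tested in edgeR (0 members, against 558 genes at an unadjusted p under 0.05). The 3 lists that held with an estimated correlation, at an adjusted p = 0.0136 each, were matrix remodelling enzymes (median 0.47; 8 of 32 up adjusted over the list alone), EWS::FLI1-repressed targets (median 0.60; 5 of 29 up adjusted over the list alone, THBS1 at 2.13 among them) and integrins and matrix receptors (median 0.29; 3 of 24 up adjusted over the list alone, ITGA3 at 1.56 among them). Collagens and matrix glycoproteins had a median of 0.79 (2 of 38 up adjusted over the list alone) at an adjusted p = 0.0967 with an estimated correlation. The same adjusted p, 0.0967 with an estimated correlation, held for mesenchymal stem cell surface markers (median 0.34) and mesenchymal transition regulators (median 0.12). Fibroblast markers (0.56) and YAP and TAZ targets (0.33) had an adjusted p = 0.128 with an estimated correlation. TGF-beta genes (0.10) and contractile genes (0.15) had 0.295 as adjusted p with an estimated correlation, and mitochondrially encoded transcripts, the lower list (-0.11), had 0.692. EWS::FLI1-activated targets were not called in A673 (median -0.04, adjusted p = 0.0714, camera). COL11A1 had 0 counts in the CD73 negative cells and 78 in the positive ones, at least 25.3-fold higher against a floor of 3 counts over the group, and did not pass (edgeR adjusted p = 0.533).

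With the replicate block, 174 genes were called in A673 (143 higher, 31 lower), 17 collagens and matrix glycoproteins, 10 EWS::FLI1-repressed targets and 9 remodelling enzymes among the higher ones. Chosen after their values were seen, the blocked fit's highest genes included CD44 (2.40), RGS5 (2.17), MMP1 (2.00) and MMP3 (1.98), and its lowest TMEM145 (-1.25), PSD (-1.21) and PPP1R1A (-1.07), a regulator of protein phosphatase. LOX (1.51), TNC (0.75), FN1 (0.77), COL1A1 (1.03), COL1A2 (1.11) and TGFBI (1.13) also passed with the block. With the block and an estimated correlation, no list's adjusted p by camera lay below 0.223. The count of 174 fell to 11 when both replicate 1 libraries were left out as well, and the count without the block was 2 without CD73 negative replicate 3.

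**Figure D2:**
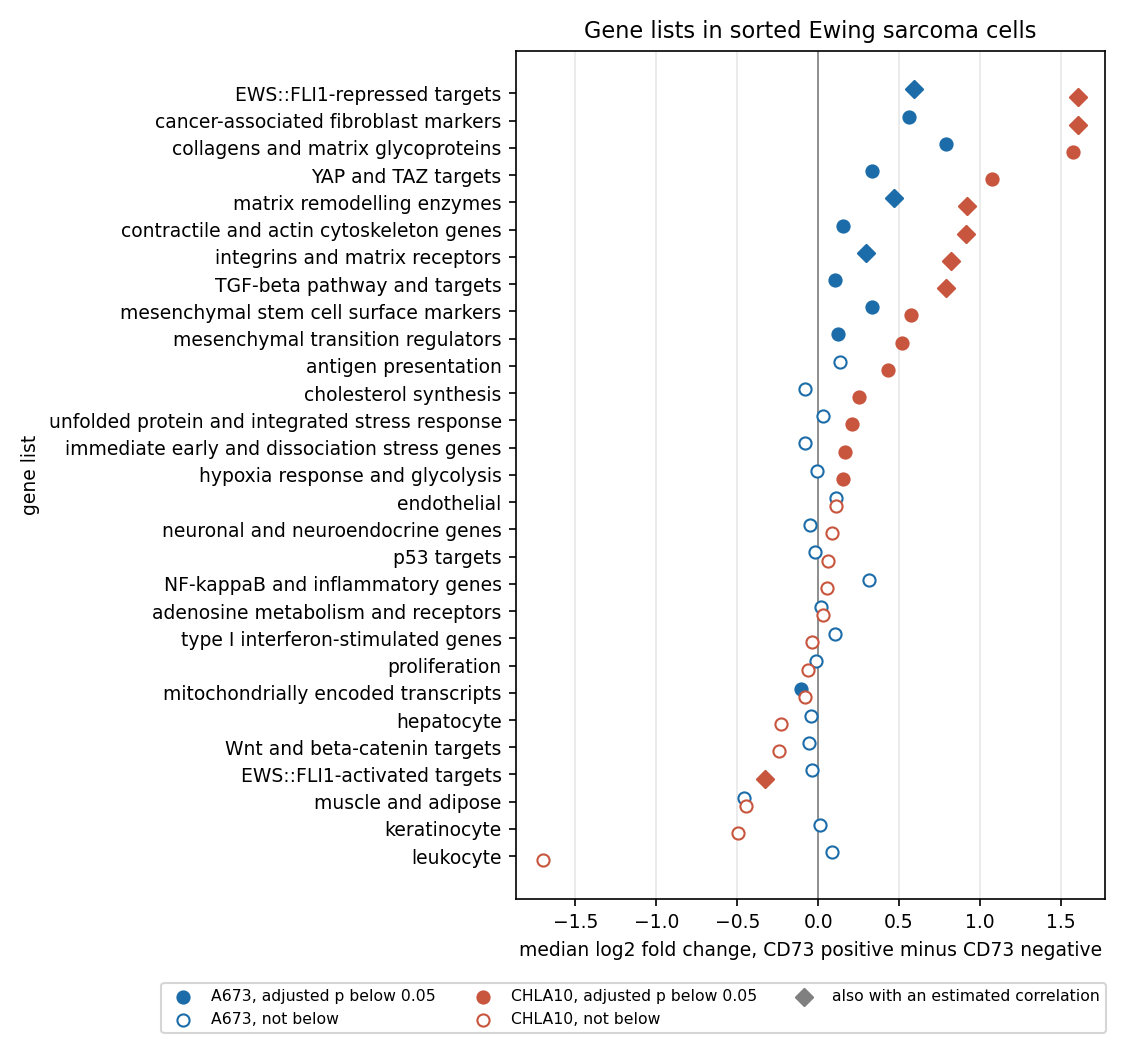
Median log2 fold change between CD73 positive and negative cells (horizontal axis) for each of 29 gene lists (vertical axis) in A673 and CHLA10, with filled points at an adjusted p below 0.05 by camera and diamonds where the call held with an estimated correlation. The matrix, adhesion and EWS::FLI1-repressed lists lie to the right in both lines, with medians up to 0.79 in A673 and up to 1.61 in CHLA10.

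The next question was whether CD73 marked the same difference in both lines. The only gene that passed in both was NT5E, against 124 with the replicate block, of which 107 were higher (20.1 expected by chance overlap) and 17 lower (3.49 expected). The 888 other genes higher in CD73 positive CHLA10 cells had a median of 0.17 in A673, where 80.2% had the same sign (camera p = 7.72e-21, and p = 0.0315 with an estimated correlation). The 513 lower ones had a median of -0.08, with 63.5% of the same sign (camera p = 5.01e-04, and p = 0.474 with an estimated correlation). With the block and an estimated correlation these p were 0.179 and 0.510. Across the 1401 genes, which are not independent replicates, the fold changes of the lines correlated at a Pearson r of 0.421. Over all 15633 genes besides NT5E, 56.5% had the same sign and r was 0.217.

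The CD73 effects of the lines differed for 176 genes, 124 with a higher and 52 with a lower effect in CHLA10 (edgeR's quasi-likelihood test of the difference, Benjamini-Hochberg adjusted). CAV1, the main protein of caveolae, stood at 795 and 2339 CPM in CHLA10 but at 2296 and 2359 CPM in A673 (difference 1.52 ± 0.17). The smooth muscle actin gene ACTA2 went from 33.9 to 271 CPM in CHLA10 against 12.2 and 13.6 CPM in A673 (2.85 ± 0.42), and TGFBR2 differed by 2.06 ± 0.30. OTX2 stood at 23.0 and 0.893 CPM in CHLA10 and at 128 and 109 CPM in A673 (-4.44 ± 0.95). By list, 14 of 29 were called by camera, 13 toward a higher effect in CHLA10, led by contractile genes (7 of 28 higher, 19 up and 1 down adjusted over the list alone), EWS::FLI1-repressed targets (7 of 29, 13 adjusted over the list alone) and fibroblast markers (4 of 22, 9 up and 1 down adjusted over the list alone). EWS::FLI1-activated targets had the lower effect (1 of 30, STEAP2 at -1.52; 12 down and 1 up adjusted over the list alone). None of the 14 calls held with an estimated correlation, the lowest adjusted p being 0.0642 (0 lists), and 8 of the 14 passed by fry. The count of genes was 1627 with the block, 527 by DESeq2, 88 by limma-voom and 323 without both A673 libraries of replicate 1. It lay at 50 and 51 without A673 negative replicates 2 and 3, at 38 and 57 without A673 positive replicates 2 and 3, at 98 without CHLA10 negative replicate 2, and at 45 and 43 without CHLA10 positive replicates 1 and 3.

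The lines themselves differed far more than the sorts. Among CD73 negative cells, 8902 of 15634 genes differed, 4262 higher in CHLA10 and 4640 higher in A673 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted), 4859 of them by at least 1 on the log2 scale. GALNT17, EPB41L3, SHISA9, GABRA5 (a subunit of a GABA receptor) and ARHGAP28 were read in CHLA10 at 157, 104, 84.4, 69.4 and 67.3 CPM and had 0 counts in A673, at least 3269-fold, 2158-fold, 1770-fold, 1453-fold and 1403-fold higher against a floor of 3 counts over the group. SALL1, BMP7 (a secreted growth factor), NKX2-5 (a cardiac transcription factor), RGS7BP and GALC were read in A673 at 102, 70.5, 52.6, 35.5 and 35.1 CPM and had 0 counts in CHLA10, at least 1884-fold, 1310-fold, 986-fold, 663-fold and 659-fold lower there. By list, hypoxia and glycolysis genes had the lowest adjusted p by camera, 0.0518, with 3 of 28 higher and 15 lower in CHLA10 and a median of -0.70. Line and growth medium changed together, so these differences cannot be assigned to one or the other.

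In these 3 xenografts, the tail vein tumours had lower levels of EWS::FLI1-activated and cholesterol synthesis targets than the subcutaneous tumour, and higher levels of hypoxia targets. As 1 animal makes up the subcutaneous arm, what follows describes these tumours by size and rests on no test of the routes of injection. EWS::FLI1-activated targets had a median difference of -1.18, with 15 of 27 lower and 2 higher by the rule of size. NR0B1 lay at 22.7 times the negative probe value in subcutaneous regions, at 1.71 times in liver and at 1.52 times in retroperitoneal regions, and NPY1R, a receptor for neuropeptide Y, at 19.9, 1.11 and 1.04 times. Cholesterol synthesis targets had a median of -0.59, with 7 of 23 lower by size, FDFT1 (-1.81) and SREBF2 (-1.80) among them. Hypoxia and glycolysis targets had a median of 0.86, with 5 of 25 higher by size, among them HK1 (1.82) and the glucose transporter gene SLC2A3. SLC2A3 lay at 1.39, 1.62 and 3.63 times the negative probe value in the subcutaneous, liver and retroperitoneal tumours. HK1 hardly differed on that measure, at 2.30, 2.42 and 2.47 times, and stood at 247 CPM in sorted A673 and 17.8 CPM in sorted CHLA10 cells. Neuronal and neuroendocrine (1.02, 6 of 12 higher by size), immediate early (0.85, 7 of 17), hepatocyte (1.00), endothelial (0.80) and leukocyte (1.24) lists had higher medians. Those of proliferation (-0.56), mesenchymal transition (-0.55) and collagens (-0.23) were lower. After subtraction of the negative probe value, these last 3 stood at -0.55, -1.11 and -0.35, and the leukocyte list at 0.89. For contractile genes (median 0.10, mean -0.06) and integrins (median 0.00033, mean -0.12) median and mean differed in sign. The fixed lists were looked at in the tumours after the data were seen.

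Signal over background differed between the tumours. The upper quartile of a region was 7.22 to 8.86 times the negative probe value in the subcutaneous tumour, 2.40 to 2.61 times in the liver tumour and 1.30 to 2.82 times in the retroperitoneal tumour. The negative probe value after Q3 scaling averaged 29.8 ± 2.75, 91.6 ± 3.47 and 111 ± 43.5 (SD, 4 regions each), so that a target at background reads higher in the tail vein tumours. The median level of the hepatocyte targets tested was 3.02, 2.11 and 1.59 times the negative probe value in the subcutaneous, liver and retroperitoneal tumours, that of the endothelial ones 3.35, 2.41 and 2.02 times, and that of the leukocyte ones 2.30, 1.80 and 2.40 times. NT5E lay at background, at 1.04, 0.955 and 1.41 times the negative probe value, and was above the limit of quantitation in 2 retroperitoneal regions only. After subtraction of the negative probe value, the EWS::FLI1-activated median was -1.05 and that of cholesterol synthesis -1.30, while hypoxia stood at 0.96.

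Of 10208 targets, 1318 were separated by size between tail vein and subcutaneous regions (797 higher, 521 lower). By limma's trend method with Benjamini-Hochberg adjustment the count was 4578 (3081 higher, 1497 lower), but with a lone subcutaneous animal, whose own variation was not measured, this count supports no difference between routes. Chance would separate 0.404% if regions were independent and up to 66.7% if all regions of an animal moved together. SUPT7L was the highest by size (5.12), making up 0.0248% to 0.0599% of all counts in subcutaneous and 0.481% to 2.40% in tail vein regions. NELL2 (3.74), HMGA2 (3.52), S100A11 (3.14) and CAV2 (3.04) were also higher. CES1, SIRPA and SOX1 lay near background in the subcutaneous tumour, at 1.47, 1.15 and 0.953 times the negative probe value, against 3.57, 3.23 and 4.81 times in the liver and 6.81, 2.83 and 2.04 times in the retroperitoneal tumour. CCK, which encodes the peptide cholecystokinin, was the lowest on values without background subtraction (-4.71). It lay at 144 times the negative probe value in subcutaneous regions against 1.44 and 1.83 times in liver and retroperitoneal regions. The size of this difference is therefore limited by background. FH (-4.10) and FCGRT (-4.06) were also lower. HAP1, SFRP2, MAPT and GYG2 lay at 57.9, 57.5, 44.6 and 42.1 times the negative probe value in the subcutaneous tumour and at most at 1.43 times in the others, so their differences are bounded by background. XAGE1A (-3.43) and the histone genes H3C3 and H4C6 were lower and H4C9 (3.66) was higher, but close sequence copies leave the gene uncertain. The panel genes FLI1 (-0.29), LOX (0.19), TNC (0.36), FN1 (1.04), COL1A2 (-0.28), CD44 (0.26), THY1 (-0.39), ENG (0.35) and VIM (1.28) were not separated by size. After subtraction of the negative probe value, FLI1 and LOX (-1.54 each) were separated lower and FN1 (1.66) and VIM (1.93) higher, while CD44 (-0.73), ENG (-0.11) and COL1A2 (0.08) took the other sign. With this subtraction, 2198 targets were separated by size, and the balance turned to 725 higher and 1473 lower, sharing 514 of the higher and 402 of the lower ones. The limma count was 1357 (383 higher, 974 lower), and TMM scaling gave 496 higher and 732 lower by size. These values rest on 1 subcutaneous and 2 tail vein animals, and the median over all targets was 0.17, or -0.28 after subtraction and -1.65 with area-normalised values, under which 2 targets were higher and 6880 lower by size.

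**Figure D3:**
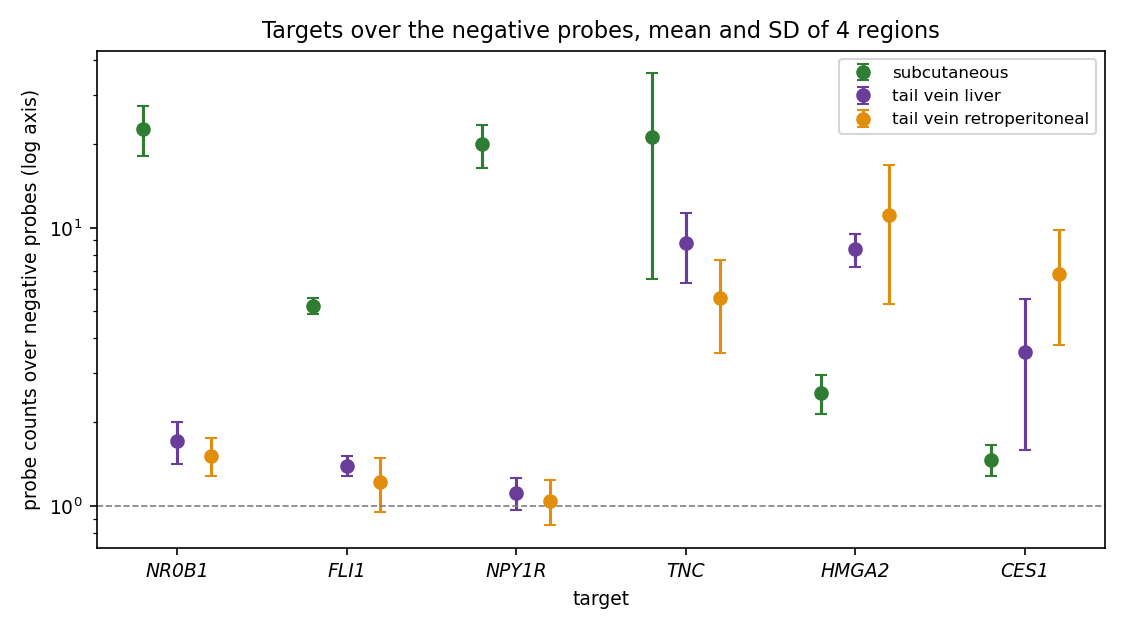
Probe counts over the negative probe value (log axis) for 6 targets in the subcutaneous, liver and retroperitoneal tumours, as mean and SD of 4 regions, with a dashed line at the negative probe value. NR0B1, FLI1 and NPY1R lay at 22.7, 5.24 and 19.9 times in the subcutaneous tumour and at most at 1.71 times in both tail vein tumours, whereas HMGA2 and CES1 were higher in the tail vein tumours.

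Set against the sorted cells, a comparison chosen after the data were seen, all 4 subcutaneous regions correlated more with CHLA10 cells (Spearman rho 0.690 to 0.704 across 11673 targets) than with A673 cells (0.601 to 0.611). All 8 tail vein regions correlated more with A673 cells (0.269 to 0.557) than with CHLA10 cells (0.218 to 0.462). Targets in a region are not independent replicates. Of 29 targets read in CHLA10 at 30 CPM or more and in A673 below 2 CPM, 27 lay above 3 times the negative probe value in the subcutaneous tumour and 0 in either tail vein tumour. Of 4529 targets expressed in both lines, 28.4% lay above it in the liver tumour and 20.5% in the retroperitoneal tumour. Their median level in CHLA10 was higher, at 77.4 CPM against 50.5 CPM for the 29. PRND, for example, stood at 37.3, 1.29 and 1.25 times, and PRRX1, a mesenchymal transcription factor, at 12.4, 0.994 and 0.902 times. Of 30 targets read in A673 only, 1 lay above 3 times in the subcutaneous, 7 in the liver and 4 in the retroperitoneal tumour (3.33%, 23.3% and 13.3%), against 92.5%, 20.9% and 15.3% of 3380 targets of like A673 level expressed in both lines. NELL2, CES1 and HMGA2, at 806, 629 and 345 CPM in A673 against 86.4, 1.99 and 40.2 CPM in CHLA10, were higher in both tail vein tumours.

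**Figure D4:**
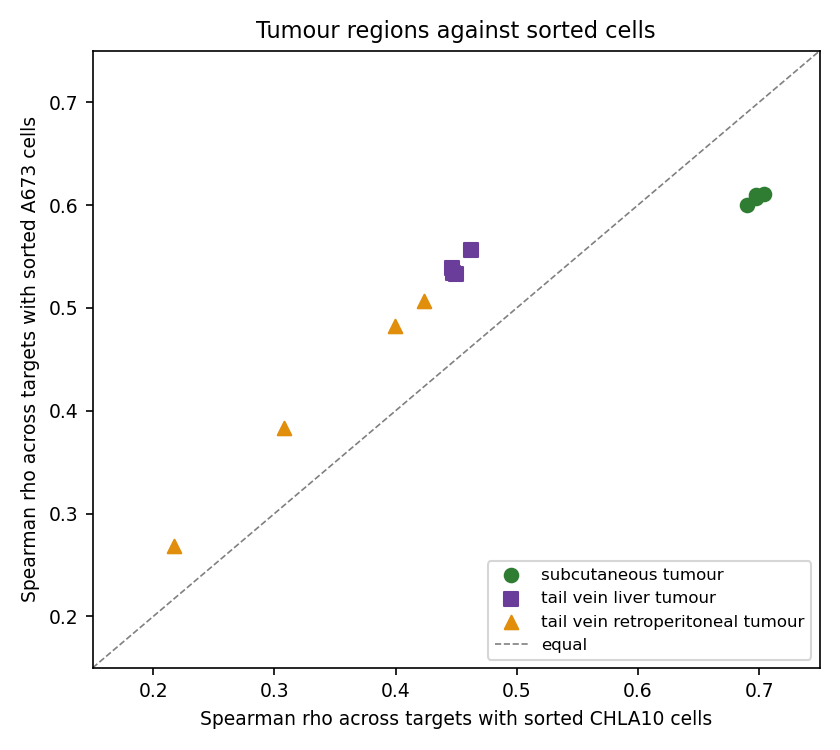
Spearman rho across targets between each of the 12 tumour regions and sorted CHLA10 cells (horizontal axis) or A673 cells (vertical axis), with a dashed line where both are equal. The 4 subcutaneous regions lie below the line, at 0.690 to 0.704 with CHLA10, and the 8 tail vein regions above it.

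Genes that marked CD73 positive CHLA10 cells were followed into the tumours, where 1 subcutaneous animal again leaves a description by size. Of 495 such genes with a log2 fold change of at least 1, 170 had a kept target, with a median difference of 0.63 between tail vein and subcutaneous tumours, and 48 were higher and 4 lower by size. FXYD5, for example, lay at 1.27, 2.06 and 3.42 times the negative probe value in the subcutaneous, liver and retroperitoneal tumours, and GNG12 at 1.60, 2.97 and 2.51 times. Of 268 genes lower in CD73 positive cells by at least 1, 142 had a kept target, with a median of 0.41, and 32 were higher and 20 lower by size. After subtraction of the negative probe value the medians were 0.25 and -0.33, against -0.28 over all targets.

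Between the tail vein tumours, 52 targets were separated by size, 21 higher in the retroperitoneal and 31 higher in the liver tumour, where chance separates 2.86% of targets if regions are independent and 100% if those of an animal move together, so that 1 animal per site allows no test. Higher in the retroperitoneal tumour were genes induced by low oxygen, DDIT4 (1.33), SLC2A3 (1.27), BNIP3 (1.26) and PDK1 (1.13), beside JAK3 (1.34), PLOD1 (1.33), LITAF (1.32), PPP2R2B (1.29), IFITM1 (1.23) and KHDRBS3 (1.98 against 0.971 times the negative probe value). Hypoxia and glycolysis targets had a median difference of 0.50, with 5 of 25 higher by size. DDIT4, SLC2A3, BNIP3 and PDK1 each read higher in regions 9 and 10 than in regions 11 and 12. DDIT4, for example, had Q3 values of 771, 330, 322 and 235 in regions 9, 10, 11 and 12. The sizes of these differences thus lean on regions 9 and 10. Their upper quartiles over the negative probe value were the lowest (2.19 and 1.30 times). Higher in the liver tumour were PENK (3.08 against 0.965 times the negative probe value), COL1A2 (-1.30), MARCKSL1 (-1.28), HNRNPA2B1 (-1.27), NT5DC2 (-1.21), SOX1 (-1.17) and the histone genes H4C13 (-1.45), H3C12 (-1.36) and H2AC13 (-1.30), again with close copies. PBRM1 (-1.58) rested on liver region 7, at 3641 against 170 to 216 in the other liver regions, and stood at -0.53 without it. The count rose to 82 without retroperitoneal region 11 and to 101 without region 12, was 47 without region 10 (39 higher and 8 lower), and shared 16 of 55 targets when regions 9 and 10 were left out.

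Regions of the same tumour varied by gene group. Of 28 lists, 15 had a median SD between regions at or above a level that 1 in 40 matched random lists reach, so that 0.7 are expected by chance. Collagens and matrix glycoproteins varied with a median SD of 0.37 against 0.22 in random lists, fibroblast markers with 0.37 against 0.21, and hypoxia and glycolysis with 0.35 against 0.20. Hypoxia targets also moved together, at a mean pairwise Pearson r of 0.475 (100th percentile), as did collagens (0.307, 100th percentile) and cholesterol synthesis (0.240, 100th percentile). After subtraction of the negative probe value hypoxia stayed at the 100th percentile (0.561), whereas collagens (77.8) and cholesterol synthesis (94.6) fell below that level, and 1 of the 8 lists that reached it in r was left. The genes higher and those lower in CD73 positive CHLA10 cells were both at the 100th percentile of spread, and at 75.6 and 89.1 after subtraction. In single tumours 15 lists reached that level in the subcutaneous, 5 in the liver and 6 in the retroperitoneal tumour, and 5 did after subtraction of the negative probe value.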

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

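The counts under other splits of the libraries, and the reading of A673 replicate 1 in them, were chosen after the result was seen. Of 126 groups of 4 regions tested for a region far from the other 3, 9 held one, where chance alone gives about 6.3. In the retroperitoneal tumour, region 10 was the highest for NR0B1 (a Q3 value of 289), LOX (160), CD44 (162) and the mean log2 of mesenchymal stem cell surface markers (7.71), and this region also had the lowest upper quartile over the negative probe value (1.30). The negative probe value itself read 175 there after Q3 scaling, so LOX and CD44 lay below background and their high values show no high expression. Subcutaneous region 2 was the highest for COL1A1 (155) and for the upper quartile over the negative probe value (8.86). In the liver tumour, region 6 was the lowest for CD44 (120), region 8 the lowest for the mean log2 of type I interferon-stimulated genes (7.06) and region 5 the highest for that of hypoxia and glycolysis (8.51).

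A difference between the CD73 effects of the lines was found for 176 genes by the test of that difference. Among 100 splits of the libraries within each line, the real one included, 6 gave 176 genes or more and the highest other gave 929. The 5 higher splits, with 929, 795, 512, 403 and 338 genes, all kept the CHLA10 groups whole and mixed the A673 labels, so they still hold the CD73 effect of CHLA10, which is the structure they show. The other splits gave at most 2 genes. The count of 6 therefore leaves open whether chance made the difference, and is no evidence for it. Of the 15 drawn splits that part all 6 same-numbered pairs, 2 reached 176, the real one and the one with 338, which also kept the CHLA10 groups whole, and with the replicate block 1627 genes were called. For the other comparisons the 10 splits are too few for a share under 0.05. The real split and the highest other gave 1402 and 1 genes in CHLA10, 1 and 0 in A673 and 8902 and 0 between the lines (edgeR), and 1 of 10 splits reached the real count in each.

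The genes with the highest differences in effect were CARD10 (5.20), COL12A1 (4.44), MAML2 (4.13), ZNF462 (3.94) and ITGA11 (3.78), and those with the lowest were UNC5D (-5.69), CACNA1A (-5.17), ARPIN (-4.80), OTX2 (-4.44) and TFAP2B (-4.19). Of these, 4 rest on 1 to 3 counts in a CHLA10 group, and their fitted values depend on the prior count. The raw ratio between the CHLA10 groups was 61.2 for CARD10 (95% Clopper-Pearson interval 10.6 to 2458), 20.1 for ZNF462 (3.21 to 832), 50.8 for UNC5D (13.7 to 425) and 36.2 for ARPIN (12.1 to 178), the last 2 being higher in CD73 negative cells.

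The lists with a different effect had median differences of 0.64 for collagens and matrix glycoproteins, 0.41 for matrix remodelling enzymes, 0.78 for fibroblast markers, 0.34 for mesenchymal stem cell surface markers, 0.85 for EWS::FLI1-repressed targets, -0.29 for EWS::FLI1-activated targets and 0.86 for YAP and TAZ targets. Those of TGF-beta genes (0.65), antigen presentation (0.27), hypoxia and glycolysis (0.19), contractile genes (0.74), integrins (0.46), immediate early genes (0.12) and cholesterol synthesis (0.37) differed too. With an estimated correlation, the adjusted p of these 14 lists lay between 0.0642 and 0.604 by camera.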

How the results depend on the processing

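Leaving out both A673 libraries of replicate 1, subtracting the negative probe value and leaving out retroperitoneal regions 9 and 10 were chosen after the results were seen, whereas the other settings were planned. For the main counts and medians, 243 of 304 values under alternatives stayed within the limits set, 59 moved and 2 passed where the planned fit did not. For named genes of the sorted cells, 5881 of 6425 kept their direction and side of the threshold, 370 fell below it, 174 rose past it and 0 turned. For named targets of the tumours, 3122 of 3424 stayed within the spread between regions, 294 moved beyond it and 8 of targets separated by size changed sign (a change of sign in a target not separated is not counted here). With the replicate block, counts were 174 in A673, 3958 in CHLA10, 1627 for the difference between lines and 124 in both lines. With both A673 replicate 1 libraries left out they were 2266 in CHLA10 and 323 for the difference, and with the block besides 11, 3737, 1123 and 10. DESeq2 gave 33 genes in A673, 527 for the difference and 25 in both lines, limma-voom 3, 88 and 3. In A673 and in both lines, 2 genes passed with no filter and 2 with the other counting column, and 0 with each line fitted alone (edgeR; 439 at an unadjusted p under 0.05 in A673). FDR 0.01 left 616 genes in CHLA10 and 31 for the difference, and a log2 fold change of at least 1 left 764 in CHLA10 and 4859 between the lines. Camera with an estimated correlation called 3 lists in A673, 7 in CHLA10 and 0 for the difference, fry 4 in A673 and 9 for the difference. Leaving out 1 library gave 1 to 2 genes in A673, 754 to 1758 in CHLA10, 38 to 232 for the difference, 7888 to 9319 between the lines and 1 to 2 in both, and 8 to 12, 14 to 16 and 11 to 15 lists. In the tumours, limma called 7616 targets with no filter, 2076 with 4 times the negative probe value and 1357 after its subtraction. By size, the tail vein comparison gave 3162, 694 and 2198 under these settings, 6882 with area-normalised values and 3653 with a difference of at least 0.5. The comparison of tail vein tumours gave 423 with area-normalised values, 539 after subtraction and 556 at 0.5. Spread lists numbered 5 after subtraction, 5 in the liver tumour alone and 6 in the retroperitoneal tumour alone. Leaving out 1 region gave 1291 to 1367 and 47 to 101 targets by size and 14 to 17 spread lists. The median lay at 0.58 to 0.68 for the list higher in CD73 positive cells and at 0.34 to 0.45 for the lower one. With area-normalised values, which lower the median of all targets to -1.65, 8 targets higher in tail vein tumours turned: ALDOC (-0.20), JUNB (-0.18), NR4A1 (-0.0672), ZFP36 (-0.41), FGB (-0.11), FABP1 (-0.55), SOX18 (-0.20) and CD163 (-0.57). For all of these changes the cause was not tested. Signal over background limits the tail vein regions most, down to 1.30 times the negative probe value.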

Other observations

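The tests of matched lists, of library size and of the shift shared by both lines were chosen after the result was seen, whereas those of line-specific targets, gene length and CHLA10 cells in replicate 1 were written before. Among 25 lists compared with random lists matched on subcutaneous level and on the ratio between the sorted lines, hypoxia and glycolysis (100th percentile), antigen presentation (99.98), immediate early genes (99.95), contractile genes (99.73) and TGF-beta genes (98.74) lay high in the tail vein tumours after subtraction of the negative probe value. Cholesterol synthesis (0.07) lay low, as did proliferation (2.43). The genes higher in CD73 positive CHLA10 cells lay at the 100th percentile, with a median of 0.29 against -0.23 in random lists, and those lower in them at 1.77, with -0.25 against -0.05. These medians were not computed like the 0.25 and -0.33 given for the same lists in the Results.

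In CHLA10, CD73 positive cells had CRYAB, a chaperone of muscle and lens, at 127 CPM against 3.65, and HMGA2, a chromatin protein of embryonic and mesenchymal cells, at 66.6 CPM against 13.7. In A673, HMGA2 stood at 338 and 352 CPM in CD73 negative and positive cells, and CRYAB at 0.354 and 2.22 CPM. TWIST1, a regulator of mesenchymal transition, lay at 39.3 times the negative probe value in the subcutaneous tumour and at 1.98 and 1.74 times in the liver and retroperitoneal tumours, while EMCN, an endothelial sialomucin, lay at 1.89, 3.64 and 3.97 times. EMCN was also read in the sorted tumour cells, at 30.8 CPM in A673 and 0.331 CPM in CHLA10, so its rise need not mean more vessels.

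EWS::FLI1-activated targets were lower in both tail vein tumours. The list's background-subtracted median lay at percentile 0.44 of random lists matched on subcutaneous level. When the ratio between the sorted lines was matched too, it lay at percentile 0.56. In these tumours the list thus fell further than most lists of like level. Random lists take targets as independent, however, and hold no variation between animals. The percentiles therefore exclude neither lower signal over background nor the difference between the lines as the whole cause. A candidate explanation that stays open is that the tail vein tumours hold cells closer to A673 than to CHLA10. A673-specific targets exceeded CHLA10-specific ones by 3.79 on the log2 scale in the tumour where the difference was smaller. Yet targets read in A673 only had medians of 1.74, 1.75 and 1.71 times the negative probe value in the subcutaneous, liver and retroperitoneal tumours. Targets of like A673 level in both lines stood at 6.16, 1.97 and 1.76 times. The value of 3.79 thus cannot separate a gain of A673 targets from the loss of signal in tail vein regions, and decides nothing. NR0B1 and NPY1R, 2 members of the list, stood at 221 and 405 CPM in sorted A673 cells. In the liver tumour they lay at 1.71 and 1.11 times the negative probe value. Of 3380 targets of the level of those read in A673 only, but expressed in both lines, 20.95% lay above 3 times there. Those targets had a lower A673 level, at a median of 62.7 CPM, so their share does not tell how often targets like NR0B1 and NPY1R would lie near background. The low values of these 2 targets therefore decide nothing about an exchange of lines. Route, site, day and cell number differed as well and stay open as untested biological explanations.

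Both A673 libraries of replicate 1 stood apart from replicates 2 and 3, with GPR174 (3.65), FLNC (3.39), COL16A1 (3.25) and TGFBI (3.19) higher, and GATA3 (-4.31), KIF21A (-4.22), DSG2 (-4.13) and EFNB2 (-4.02) lower on the log2 scale. The tables argue against library size, as 2 of the 2 libraries lay inside the range of the others, and against gene length, whose Spearman correlation with the difference was 0.0636 across 15620 genes. They also argue against CHLA10 cells mixed in, since 13 genes specific to CHLA10 reached a median of 0% of their CHLA10 level. A different day, culture or passage may stand behind replicate 1 and stays open, as the labels name none, and no biological explanation was tested.

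The genes called by CD73 in CHLA10 tended to have the same sign in A673. A shift shared by the CD73 positive cells of both lines may lie behind this, and the test cannot settle it. With an estimated correlation the camera p was 0.0315 for the higher genes, against 0.179 with the replicate block and 0.474 for the lower genes. It stays open because genes move together within so few libraries. The sort itself, which placed NT5E higher in both lines, applies to both alike.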
